A study of Homo sapiens with 35 samples.

How the data were processed

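Kidney messenger RNA was measured in 35 libraries from ewes before pacing, in heart failure after 14 days of rapid pacing, and in recovery 25 days after pacing stopped. The organism field of the record reads Homo sapiens, while the protocols describe Coopworth ewes and the gene names are in the style of the sheep annotation, so the values were read as sheep. No sheep genome was at hand, so no coordinates are given. The authors deposited a table of raw counts per gene, with 31553 genes, of which 2585 were at 0 in every library, 15374 had LOC identifiers and 21 had names altered into dates. Per the labels, stranded poly(A) libraries were made and FastQC, Bowtie2, TopHat2 and bedtools were used, with no versions or genome build stated. The values were whole numbers that summed to a different total in each library.

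Groups were taken from the sample titles. For 2 libraries, baseline 8 and heart failure 7, the time point label reads recovery, against the title. Those labels were tried as an alternative grouping, and both libraries were left out in another. The series text speaks of 6 ewes sampled serially, with 5, 6 and 5 samples, while 7 animal tags recur between groups, 5 of them in all 3. No label states which samples were biopsies and no sequencing batch is given, so a recurring tag was used as a stand-in. Total counts in M (mega-counts) ran from 15.4 to 21.1 M in baseline, 18.0 to 22.6 M in heart failure and 14.3 to 20.3 M in recovery. In 197 pairs of libraries within groups, the variance over 13646 genes was at least 19.8 times sampling noise (median 81.6), so no library was a copy of another of its group.

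Counts were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood with robust dispersion, TMM factors and the package's filter on low counts by group. All p-values are two-sided, and genes past a Benjamini-Hochberg adjusted p of 0.05 over all genes tested were called. The 3 pairwise comparisons, 1 test over the 3 groups, the genes called in opposite directions in heart failure and recovery, and tests of the shared tag were fixed before the data were examined, as were 37 gene lists, 20 named genes and the alternatives, except where stated. Log2 values of single libraries used a prior count of 2. A library was taken to show a gene's direction when it lay beyond the mean of the group it was compared with. Lists of at least 5 tested genes were tested by camera with a correlation of 0.01, by camera with an estimated correlation and by fry in limma 3.58.1, which left 36 lists. The erythroid list was too small to test, and 2 genes of the lists were matched through another spelling or an older symbol.

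The genes named are the 10 with the highest and the 10 with the lowest log2 change among those called with a symbol and a mean log2 CPM of at least 1, the 20 genes named in advance, of which 19 were in the table, and up to 4 members of each list with the smallest p. For the opposite-direction test they are the 10 with the strongest evidence, and for the tag tests the 5 highest and 5 lowest. HAVCR1, a kidney injury gene, was not in the table.

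Baseline 2, 12 and 14 lay over 2 log2 units below the median of all libraries in their proximal tubule markers. They were kept in the tests fixed in advance, and a set of 32 libraries without them, chosen after seeing the data, was put through every test and alternative. The alternatives were the animal tag as a fixed block or as a random block in limma-voom, terms for a shared tag or a presumed biopsy, libraries with shared or own tags alone, the 2 label choices, RLE and upper-quartile factors, DESeq2 1.42.0, no filter and a filter of 1 CPM in 8 libraries, 2 surrogate variables from sva 3.50.0, a log2 change of at least 1, and each library left out in turn. A medullary covariate was added for the 32 libraries after seeing the data. Under the fixed block, a library whose tag occurs once in the fit adds nothing to the group differences. Fewer libraries therefore stand behind its counts than behind those without a block. As a check of the pairing, residuals of libraries with the same tag correlated at a mean of 0.195 (lowest -0.014, highest 0.4, 14 pairs) against -0.008 in 321 other pairs, and 10 of 16 libraries were closest to one with their own tag. The random block's correlation was 0.152 in the 35 libraries and 0.197 in the 32.

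Counts were simulated from the fitted dispersions with 200 genes changed, to test the procedure on simulated data. In the 32 libraries, 52.2%, 67.2% and 95.5% of genes changed 1.5, 2 and 4 times were recovered in heart failure against baseline, with 3 false among 146 calls. For recovery against heart failure these were 40.3%, 67.2% and 89.4% with 7 false of 138, and for recovery against baseline 46.3%, 59.7% and 87.9% with 5 false of 134. In the 35 libraries the values were 43.3%, 65.7% and 92.4% (2 false of 136), 29.9%, 49.3% and 87.9% (3 of 114), and 14.9%, 50.7% and 87.9% (2 of 104). A list shifted by 1 log2 unit was recovered by all 3 list tests, with 0 other lists called. This 0 does not carry over to the real libraries. With their group labels dealt again over any library, camera with its preset correlation still called many lists. The median over the 3 comparisons together was 32 list calls in the 32 libraries and 41 in the 35. The simulation therefore does not show that the list tests hold on these data. It drew each gene independently, so its few false gene calls need not hold either. With labels dealt again, edgeR called a median of 113 genes (highest 593) in heart failure against baseline of the 35 libraries. In the 32 the median was 0 (highest 30).

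Some gene names may have gathered reads of other genes, though the reads themselves were not examined. FANCC, ATRNL1, ZNF10 and LOC101120236 followed the abundant EEF1A1 over the 35 libraries (Pearson r from 0.989 to 0.994), and DNAH14, at a mean of 54560 CPM, followed the sum of 13 mitochondrial genes (r = 0.976). None of these is named as a result. A few genes that the rules name are not reported here.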

Results

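Messenger RNA of sheep kidney was sequenced in 35 libraries taken around an episode of heart failure. The ewes' hearts were paced fast for 14 days, which brings on acute decompensated heart failure, and were then left unpaced for 25 days. By their titles, 14 libraries were baseline, 13 were heart failure and 8 were recovery. Total counts per library averaged 18.3 M (mega-counts) in baseline (SD 1.8, n = 14), 19.6 M in heart failure (SD 1.2, n = 13) and 18.3 M in recovery (SD 2.1, n = 8). Single libraries ran from 14.3 M to 22.6 M. Of the 35 libraries, 19 carried an animal tag found in more than 1 group and 16 carried a tag of their own. In the protocol, animals followed over time gave needle biopsies at baseline and heart failure and gave their recovery sample after euthanasia, and other animals gave post-mortem tissue. The labels do not say which library was collected in which way.

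3 of the 14 baseline libraries held few kidney transcripts. UMOD, the uromodulin gene of the thick ascending limb, stood at 0.122, 0.191 and 2.98 CPM (counts scaled to the library total) in baseline 2, 12 and 14, against a median of 1600 CPM (lowest 230) in the other 32 libraries. SLC34A1, the proximal tubule phosphate transporter, stood at 0.122, 0.127 and 9.41 CPM against a median of 314 CPM. Baseline 2 instead carried genes of adrenal steroid synthesis, with STAR at 4230, CYP17A1 at 5180 and HSD3B1 at 15500 CPM, where the highest of the 32 reached 6.09, 3.06 and 8.97 CPM. Baseline 12 carried skeletal muscle and fat genes, with TTN (titin) at 15800, ACTA1 (skeletal actin) at 5290 and ADIPOQ (adiponectin) at 1820 CPM. Baseline 14 carried keratin genes of stratified epithelium and smooth muscle genes, with KRT6A at 6940, KRT14 at 5090 and MYH11 (smooth muscle myosin) at 11500 CPM. The median log2 CPM of the proximal tubule list was 0.87, -0.66 and 5.21 in baseline 2, 12 and 14, and ran from 7.08 to 8.59 in the other 32. All 35 libraries entered the tests fixed in advance. The 32-library tests, which leave out these 3, were chosen after the data had been seen, and both are given for each comparison. Among the 32, baseline 13 was highest in DES (desmin, 383 CPM, median 19.5), MYH11 (468, median 57.9) and TTN (19.4, median 0.913). Its matrix list stood at a median log2 CPM of 6.29 and its pericyte and smooth muscle list at 5.05, both the highest of the 32 (medians 5.01 and 4.38).

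**Figure D1:**
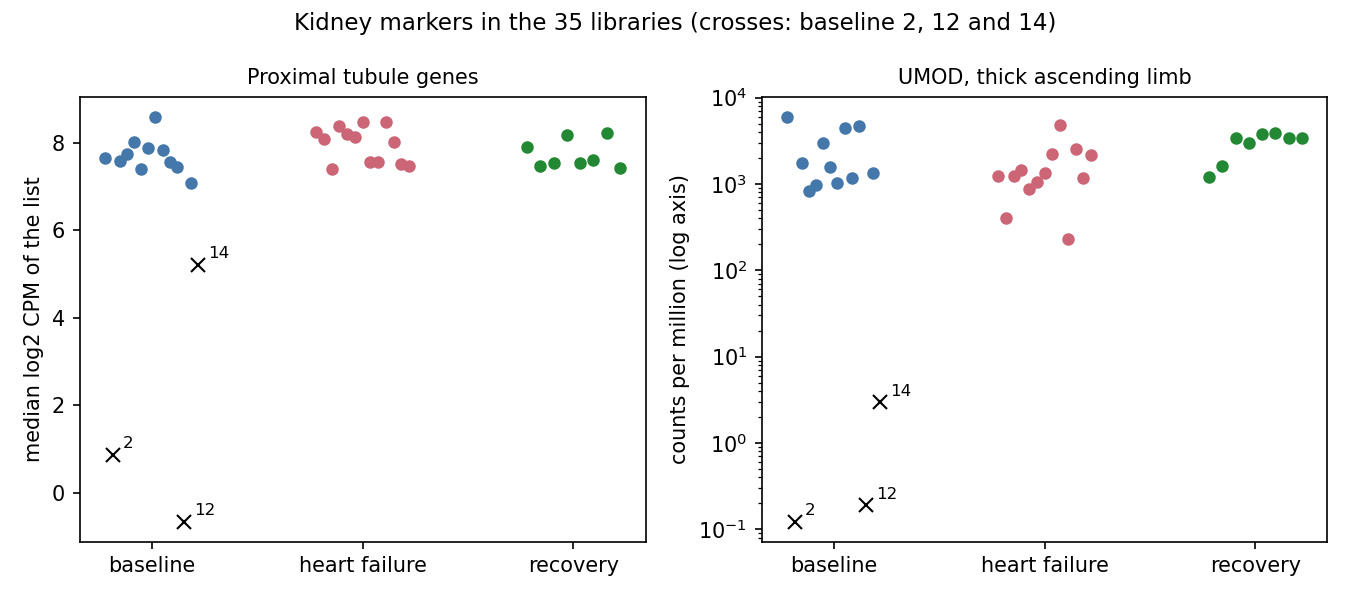
Median log2 CPM of the proximal tubule list (left) and UMOD in CPM on a log axis (right), 1 point per library, for 14 baseline, 13 heart failure and 8 recovery libraries. Crosses mark baseline 2, 12 and 14, which lie below all 32 others in both panels.

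The comparison of heart failure with baseline asks which kidney genes differed once heart failure had developed. With all 35 libraries, the inducible heat shock gene HSPA6 rose by 3.57 on the log2 scale (SE 0.74, adjusted p = 0.00625, higher in 10 of 13 heart failure libraries). The adhesion molecules of activated endothelium, P-selectin (SELP, 2.15) and ICAM-1 (2.00), rose in 13 of 13, and the stress-induced transcription factor ATF3 (1.78) in 10 of 13. The interferon-induced kinase EIF2AK2 (1.80), the monocyte chemokine CCL8 (2.00), the matrix protease ADAMTS4 (2.89), the secretin receptor SCTR (2.02) and the sulfotransferase SULT6B1 (1.94) were also among the 10 highest. The 10 genes that fell most were muscle, keratin and steroid genes, led by ACTA1 (-11.73), TTN, KRT17 (-10.18), KRT6A (-9.98) and MYL1 (-9.78), followed by KRT15, STAR, TNNT1, RYR1 and ATP2A1 (-9.55 to -9.07). Of the marker lists, skeletal muscle had 12 of 14 members lower, adipocyte 9 of 15 and adrenal 4 of 6. Genes of these tissues stood high in baseline 2, 12 and 14. Of 50 oxidative phosphorylation genes 12 fell (41 adjusted over the list alone), of 25 cholesterol genes 9 fell (18 adjusted over the list alone) and of 38 cell cycle genes 7 fell (31 adjusted over the list alone). The oxidative phosphorylation list stood above the highest of the other 32 (6.26) in all 3 libraries, at 6.77, 7.32 and 6.43 in baseline 2, 12 and 14. The cholesterol list did so in baseline 2 (6.71) and 14 (5.16) but not 12 (4.03), against 4.90, and the cell cycle list only in baseline 14 (4.81), against 3.32. Without the 3 libraries 1, 3 and 0 of these genes fell (4, 3 and 0 adjusted over the list alone, 16, 8 and 8 at an unadjusted p under 0.05, cell cycle 1 higher in DESeq2). Of 29 cytokine genes 9 rose and 1 fell (13 and 2 adjusted over the list alone), and of 33 interferon response genes 6 rose and 1 fell (15 and 1 adjusted over the list alone). Camera called 19 lists, 13 up and 6 down, with oxidative phosphorylation down at 2.53e-16, cholesterol down at 1.2e-06 and cytokines up at 5.34e-05. These had adjusted p = 0.572 with an estimated correlation. Cell cycle was down at 0.000602 and interferon up at 2.49e-06, with adjusted p = 0.693 and 0.58 with an estimated correlation. Under that setting and in fry 0 lists were called (0 and 10 at an unadjusted p under 0.05).

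In edgeR's quasi-likelihood test on 35 libraries, 1217 of 20775 genes passed a Benjamini-Hochberg adjusted p of 0.05, 258 higher and 959 lower (5045 at an unadjusted p under 0.05). Leaving out baseline 2, 12 and 14 turned this into 416 genes, 207 higher and 209 lower, of which 239 were shared by both fits. With the animal tag as a fixed replicate block 0 of the genes passed in the 35 libraries (1752 at an unadjusted p under 0.05). With the tag as a random block in limma-voom 268 did. Removing single libraries gave 564 genes without baseline 12, 719 without baseline 14 and 775 without heart failure 5.

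In the 32 kidney libraries, 7 of 33 heat shock genes and 5 of 36 immediate early genes were higher in heart failure, and 4 of 24 principal cell genes and 3 of 25 cholesterol and SREBP genes were lower. SREBF1, the transcription factor that turns on fatty acid synthesis, fell by 0.83 (SE 0.16, adjusted p = 0.00861, lower in 13 of 13), from 25.2 CPM (SD 4.91, n = 11) to 14.2 CPM (SD 3.39, n = 13). AQP2, the water channel of the collecting duct that answers to vasopressin, fell by 0.74 (SE 0.20, adjusted p = 0.0465, lower in 13 of 13), from 1940 CPM (SD 675) to 1163 CPM (SD 433). Heart failure 10 counted as lower at 10.78 log2 CPM against a baseline mean of 10.79. Between baseline 8 and heart failure 7, of the same tag, AQP2 went from 11.00 to 9.25 log2 CPM. In the other tags with kidney libraries in both groups it went from 10.27 to 10.22, 10.47 to 10.43, 10.72 to 10.78 and 9.55 to 9.72. The urea transporter SLC14A2 fell by 2.02 (adjusted p = 0.0399), but 7 of the 11 baseline libraries also lay below the baseline mean of 3.70 log2 CPM (SD 1.65, 2.13 to 6.71). The vasopressin receptor AVPR2 fell by 0.91 (adjusted p = 0.0481, lower in 12 of 13).

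The highest log2 changes among genes that passed included HSPA6 (3.94), the orphan nuclear receptor NR4A3 (3.42), ADAMTS4 (3.13), NR4A1 (2.60) and the immediate early factor FOS (2.58). Next came SMTNL1 (2.50), SELP (2.35), ATF3 (1.89) and RGS16 (1.82), a brake on G protein signalling. SMTNL1, SELP and RGS16 were higher in 13 of 13 heart failure libraries, but NR4A1 in only 8 of 13 and HSPA6 in 10 of 13. The lowest were the mucosal peptide TFF3 (-4.54), FCGBP (-3.44), the BMP antagonist GREM1 (-3.41), CAPN8 (-2.69) and OLFM4 (-2.56). Next came the T cell chemokine CXCL9 (-2.49), SLC14A2, the tubule patterning ligand WNT9B, the prostaglandin E2 receptor PTGER1 (-1.90) and RASAL1 (-1.75). Of these lowest genes only PTGER1 still passed with the animal tag as a random block. TFF3 and FCGBP were also among the genes that stood highest in shared-tag against own-tag libraries. Among the genes named in advance, the loop of Henle salt transporter SLC12A1 (-1.32, adjusted p = 0.0743, lower in 11 of 13) and UMOD (-0.59, adjusted p = 0.425) did not pass. The kidney injury gene LCN2 (0.01), the collagen gene COL1A1 (0.21), the peptidase ACE (0.31), the receptor AGTR1 (-0.30) and the natriuretic peptide receptors NPR1 (0.09) and NPR3 (0.08) did not pass either.

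By gene group, 7 of 33 heat shock and unfolded protein genes rose and 0 fell (20 higher adjusted over the list alone), among them the chaperones HSP90AA1 (0.74, adjusted p = 0.00959, higher in 12 of 13) and HSPH1 (1.05, adjusted p = 0.024, higher in 11 of 13). Of 36 immediate early genes 5 rose, JUNB by 1.73 (adjusted p = 0.0138, higher in 13 of 13), and KLF4 fell (-1.02) (26 higher and 2 lower adjusted over the list alone). Of 29 cytokine genes 3 rose, SELP, ICAM-1 (1.78) and the B cell factor TNFSF13B (0.85), and CXCL9 fell (13 and 1 adjusted over the list alone). Of 25 complement and acute phase genes 2 rose, the C1 inhibitor SERPING1 (1.34, adjusted p = 0.00881, higher in 13 of 13) and complement factor I (CFI, 0.63) (4 higher and 1 lower adjusted over the list alone). Of 20 loop of Henle genes 3 fell, PPP1R1A (-1.33), SLC14A2 and the tight junction gene CLDN19 (-1.11) (9 adjusted over the list alone). Of 24 principal cell genes 4 fell, AQP2, AVPR2, SLC14A2 and the transcription factor ELF5 (-0.95) (1 higher and 7 lower adjusted over the list alone). Of 25 cholesterol and SREBP genes 3 fell, SREBF1, the fatty acid elongase ELOVL6 (-0.78) and fatty acid synthase (FASN, -0.55) (3 adjusted over the list alone). The list of 18 medullary genes, whose genes depend on how much medulla a sample held, had HSPA1A higher (1.25) and SLC14A2 and AQP2 lower (1 and 5 adjusted over the list alone).

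Camera with a preset correlation of 0.01 called 13 of 36 lists in the 32 libraries, 7 up and 6 down. It put the heat shock list up at adjusted p = 1.05e-11, immediate early genes up at 3.58e-08, cytokines up at 0.000925 and complement up at 0.00252. These had adjusted p = 0.615 with an estimated correlation. It put the loop of Henle list down at 6.19e-06, cholesterol genes down at 8.87e-05 and principal cells down at 0.009. They too had adjusted p = 0.615 with an estimated correlation. With an estimated correlation 0 lists were called (2 at an unadjusted p under 0.05). Fry, which asks whether a list moves on balance, called 0 (8 at an unadjusted p under 0.05).

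The 416 genes came from edgeR's quasi-likelihood test of 20686 genes (3716 at an unadjusted p under 0.05), and DESeq2 called 1006. With the animal tag as a fixed replicate block 0 genes passed and 1092 had an unadjusted p under 0.05, where chance gives 1034. That fit draws mainly on the 5 animals with kidney libraries in both groups. Its 0 thus rests on fewer libraries than the 416, and the loss of samples cannot be told apart from an effect of the animals. Limma-voom with the tag as a random block called 488. All 59 named calls kept their direction under the fixed block, with SREBF1 at -0.52 (adjusted p = 0.828) and AQP2 at -0.33 (adjusted p = 0.956). The calls had been made on the same libraries, so a shared direction was partly built in. NR4A1 came to 0.10 (adjusted p = 0.996), NR4A3 to 0.58 (adjusted p = 0.982), FOS to 1.07 (adjusted p = 0.941) and HSPA6 to 1.90 (adjusted p = 0.948). Under the random block 38 of the 59 still passed, SREBF1 at -0.83 (adjusted p = 0.00769). NR4A1 (1.13, adjusted p = 0.367), NR4A3 (1.84, adjusted p = 0.278), FOS (2.05, adjusted p = 0.0699) and HSPA6 (1.71, adjusted p = 0.286) were among the 21 that did not. So were TFF3 (-1.66, adjusted p = 0.516), FCGBP (-1.85, adjusted p = 0.308), GREM1 (-2.62, adjusted p = 0.15), CAPN8 (-0.93, adjusted p = 0.387), OLFM4 (-1.26, adjusted p = 0.27) and SLC14A2 (-1.32, adjusted p = 0.234). The count fell to 175 genes without baseline 6, 222 without baseline 11, 240 without baseline 1, 245 without baseline 9, 261 without baseline 4, and 264 without baseline 3. It was 233 without heart failure 5, 249 without heart failure 11, 262 without heart failure 1 and 273 without heart failure 13, and rose to 761 without heart failure 10, 879 without heart failure 9 and 1142 without baseline 13. With the mean of 4 medullary genes as a covariate, added after the data had been seen, it was 235 genes. SREBF1 still passed (-0.66, adjusted p = 0.0239), while AQP2 did not (-0.78, adjusted p = 0.0559). The AQP2 fall did not shrink, as it was -0.74 without the covariate. Of the 59 named calls 32 still passed. The fall shrank in RASAL1 (-1.04, adjusted p = 0.0796), CLDN19 (-0.61, adjusted p = 0.189), WNT9B (adjusted p = 0.254) and SLC12A1 (-0.37, adjusted p = 0.321), and UMOD came to 0.01 (adjusted p = 0.994).

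The comparison of recovery with heart failure asks what changed after pacing was stopped. With all 35 libraries only FLT4, the receptor of lymphatic endothelium for VEGF-C, passed, and it fell by 1.26 (SE 0.20, adjusted p = 0.00677, lower in 8 of 8). Its mean went from 27.3 CPM (SD 6.02, n = 13) to 11.4 CPM (SD 2.24, n = 8). The edgeR count was thus 1 gene of 20775 (2228 at an unadjusted p under 0.05), against 331 in DESeq2 and 43 in limma-voom with a random replicate block. None of the 36 immediate early genes and none of the 33 interferon genes passed in edgeR over all genes (26 and 19 at an unadjusted p under 0.05, 25 and 12 lower adjusted over the list alone, 9 and 5 lower in DESeq2). Camera called 17 lists, with these 2 down at 2.8e-13 and 7.12e-10, and adjusted p = 0.294 and 0.351 with an estimated correlation. With a fixed replicate block 0 genes passed (1525 at an unadjusted p under 0.05), with FLT4 at -1.08 (adjusted p = 0.37). Removing 1 library gave more calls, with 101 genes without baseline 2, 86 without baseline 12, 57 without baseline 14, 42 without heart failure 9, and 33 without baseline 13. There were 10 without heart failure 10, 6 without heart failure 4, 3 without baseline 11 or heart failure 11 and 2 without recovery 4.

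In the 32 kidney libraries, 15 of 25 cholesterol and SREBP genes and 6 of 20 loop of Henle genes were higher in recovery, and 12 of 36 immediate early genes and 10 of 44 matrix genes were lower. SREBF1 rose by 1.20 (SE 0.17, adjusted p = 0.000492, higher in 8 of 8), to a mean of 32.7 CPM (SD 11.5, n = 8) from 14.2 CPM (SD 3.39, n = 13). PDK4, the kinase that turns cells from glucose to fat burning, fell by 3.68 (SE 0.64, adjusted p = 0.00253, lower in 8 of 8), from 245 CPM (SD 352) to 19.1 CPM (SD 8.80). SLC14A2 rose by 2.89 (adjusted p = 0.00435, higher in 8 of 8), AQP2 by 0.82 (adjusted p = 0.0259, higher in 8 of 8) and SLC12A1 by 1.69 (adjusted p = 0.0229, higher in 8 of 8). The natriuretic peptide receptor NPR1 fell by 0.60 (SE 0.12, adjusted p = 0.00606, lower in 8 of 8), from 50.4 to 33.3 CPM.

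The highest log2 changes were GPR26 (4.42), the vasa recta urea transporter SLC14A1 (4.25), RANBP3L (3.85), the ligand WNT7B of collecting ducts (3.29), SLC14A2 and WNT9B (2.83). Next came the betaine transporter SLC6A12 (2.60), RASAL1 (2.54), the incretin receptor GLP1R (2.04) and MYLK4 (1.86). The lowest included ADAMTS4 (-3.90), NR4A3 (-3.80), NR4A1 (-3.70), PDK4 and FOS (-2.95). Next came NR4A2 (-2.83), the eosinophil chemokine CCL24 (-2.81), EGR1 (-2.53) and the collagen crosslinker LOXL4 (-2.33). RANBP3L and SLC6A12 were higher in 6 of 8 recovery libraries, and each of the others shifted in 7 or 8 of 8. Among the genes named in advance, the fibrillar collagen COL1A1 fell by 1.61 (adjusted p = 0.0366, lower in 8 of 8), while COL3A1 (-1.39, adjusted p = 0.0923) and UMOD (0.86, adjusted p = 0.211) did not pass.

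**Figure D2:**
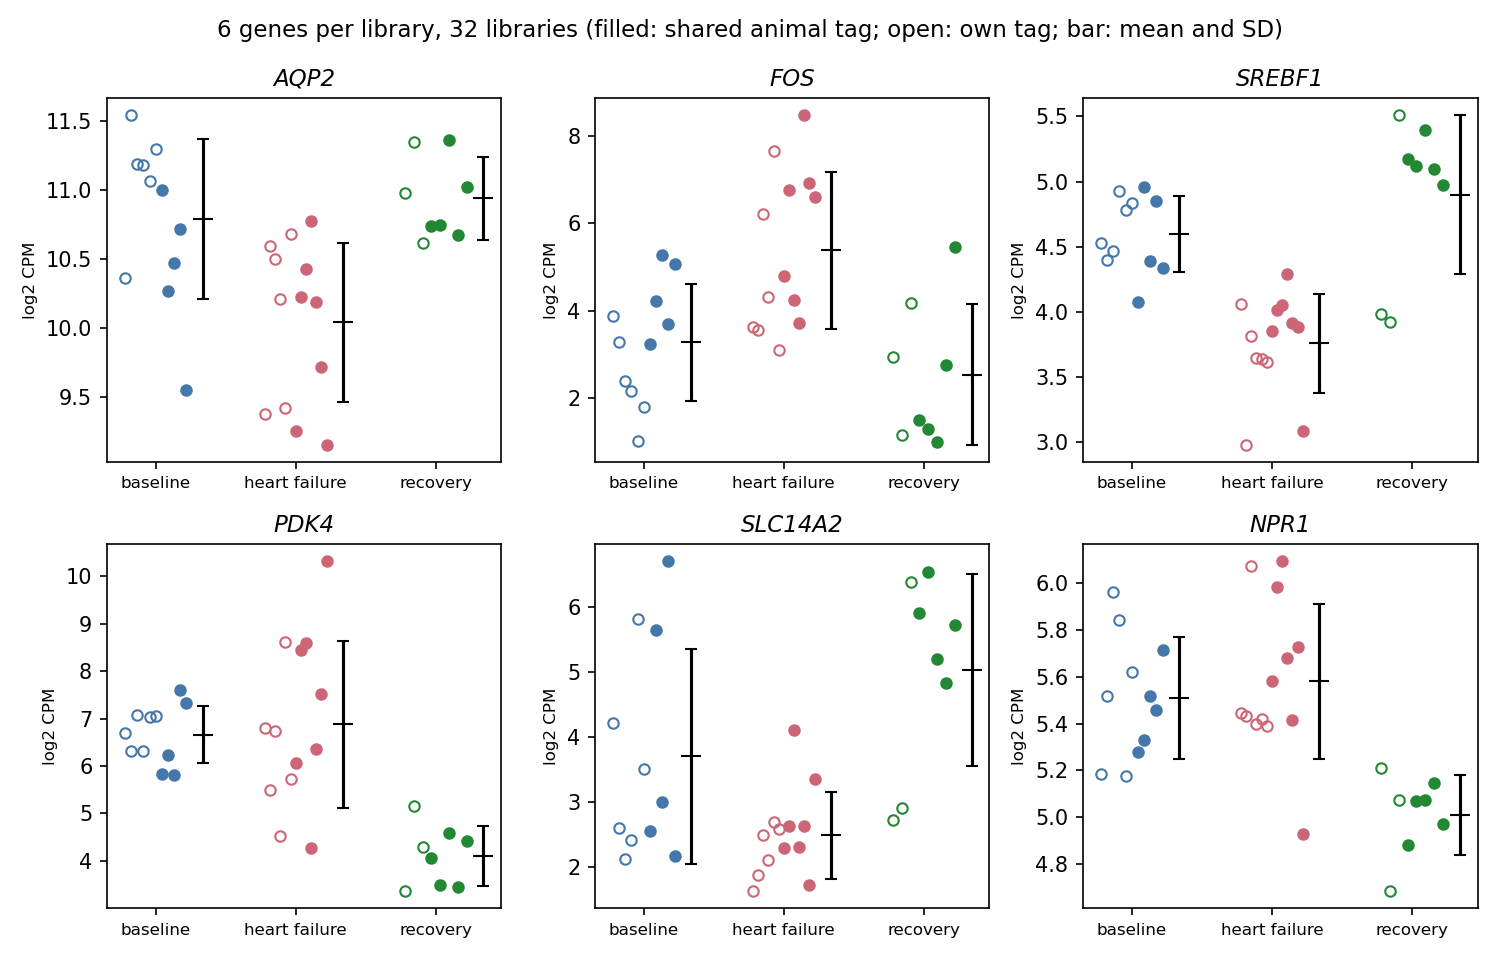
Expression of AQP2, FOS, SREBF1, PDK4, SLC14A2 and NPR1 in log2 CPM for 11 baseline, 13 heart failure and 8 recovery libraries, 1 point per library (filled, animal tag shared between groups; open, tag of its own), with the mean and SD beside each group. Mean SREBF1 was 4.60, 3.76 and 4.90 log2 CPM in baseline, heart failure and recovery.

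By gene group, 15 of 25 cholesterol and SREBP genes rose and 0 fell (16 adjusted over the list alone). Among them were ELOVL6 (1.01, adjusted p = 0.0027, higher in 8 of 8), the mevalonate enzyme MVD (0.68, adjusted p = 0.0027, higher in 8 of 8) and INSIG1 (0.83, adjusted p = 0.0056, higher in 7 of 8), which holds back SREBP. Fatty acid oxidation moved the other way, with 10 of 36 genes lower and 1 higher (12 and 3 adjusted over the list alone). Among them were PDK4, the long-chain dehydrogenase ACADVL (-0.63, adjusted p = 0.00253) and the carnitine carrier SLC25A20 (-0.78). Of 20 loop of Henle genes 6 rose (9 higher and 1 lower adjusted over the list alone), with PPP1R1A (1.36) and the potassium channel KCNJ1 (0.84). Of 24 principal cell genes 4 rose and KCNJ16 fell (-0.43) (7 and 2 adjusted over the list alone). Of 18 medullary genes 4 rose, SLC14A1, SLC14A2, SLC6A12 and AQP2 (5 adjusted over the list alone). Of 36 immediate early genes 12 fell (27 adjusted over the list alone), and 7 of 33 heat shock and unfolded protein genes fell (19 adjusted over the list alone), with the endoplasmic reticulum chaperones CALR (-0.51) and HSP90B1 (-0.51). Of 44 matrix genes 10 fell (21 adjusted over the list alone), with smooth muscle actin ACTA2 (-1.52, adjusted p = 0.00195, lower in 8 of 8) and connective tissue growth factor (CTGF, -1.38). Of 22 pericyte, mesangial and smooth muscle genes 8 fell (2 higher and 8 lower adjusted over the list alone), with TAGLN (-1.31) and MCAM (-0.92). Of 25 endothelial genes 8 fell, with EHD3 (-1.15) and the VEGF receptor KDR (-0.61), and SLC14A1 rose (10 and 1 adjusted over the list alone). Of 22 podocyte genes 3 fell, ACTN4 (-0.42), KIRREL (-0.79) and SYNPO (-0.55) (5 adjusted over the list alone).

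**Figure D3:**
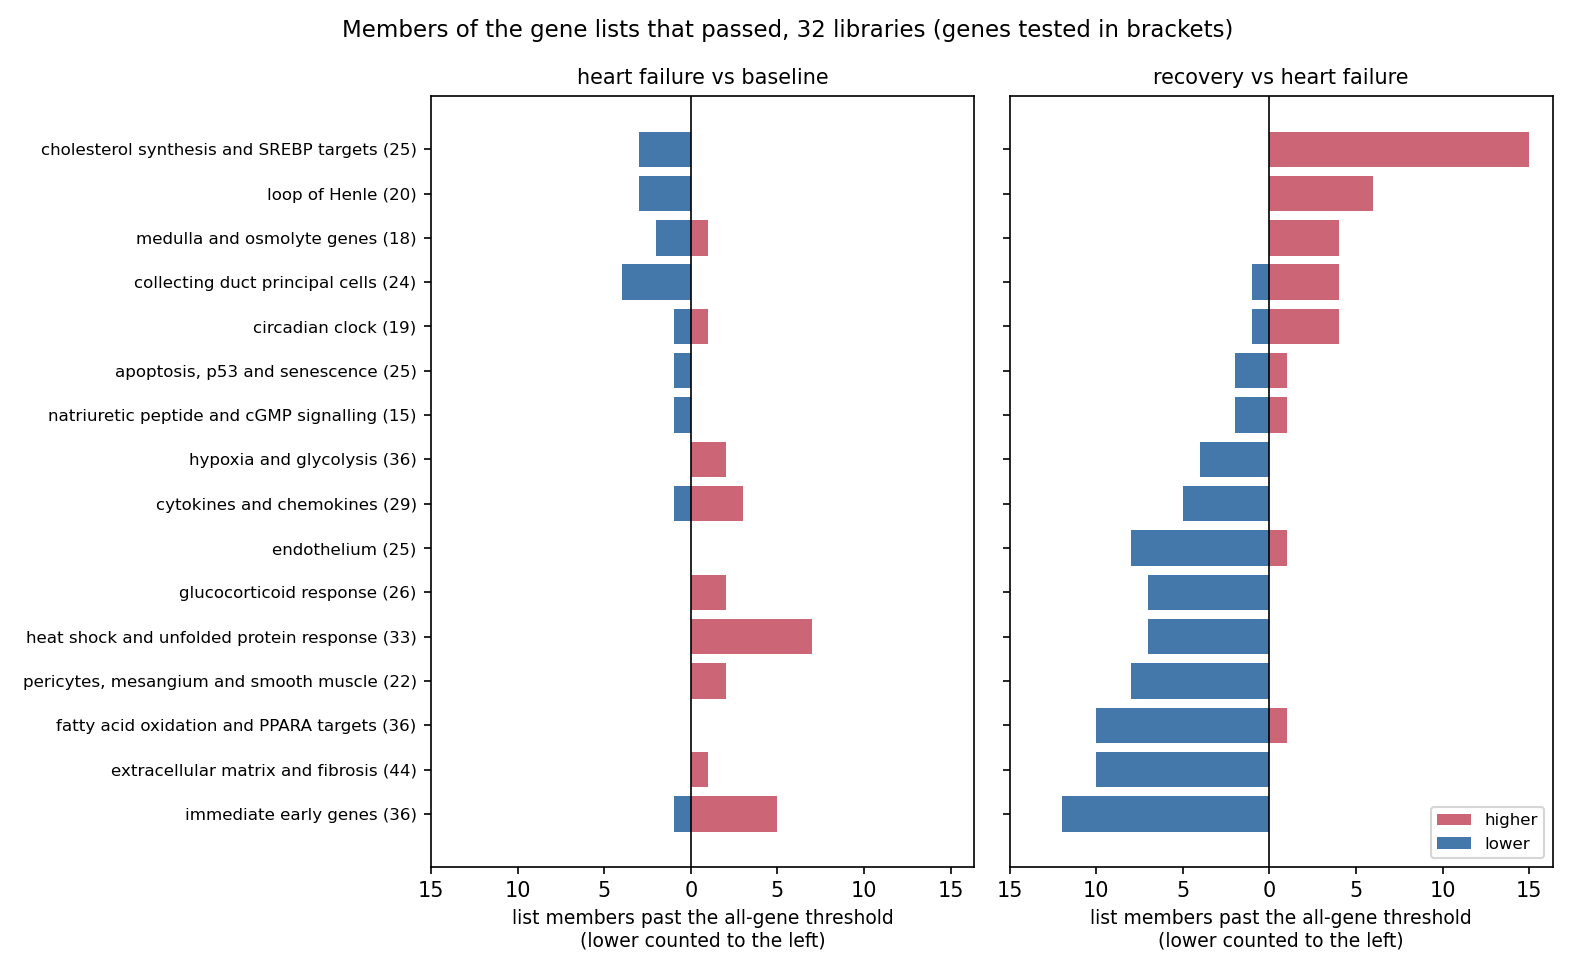
Number of genes, for each list with at least 4 over both panels, higher (right of 0) or lower (left of 0) at an adjusted p of 0.05 over all genes tested, in heart failure against baseline (left panel) and recovery against heart failure (right panel), 32 libraries. The number of list genes tested stands in brackets, and in recovery against heart failure 15 of 25 cholesterol genes were higher and 12 of 36 immediate early genes were lower.

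Camera called 17 of 36 lists in this comparison, 5 up and 12 down, and with an estimated correlation it called 0 (4 at an unadjusted p under 0.05). The cholesterol list was up at adjusted p = 2.02e-14, with adjusted p = 0.0751 with an estimated correlation and 0.000122 in fry. The loop of Henle (4.53e-08) and medullary lists (0.000116) were up, each with adjusted p = 0.306 with an estimated correlation and with 0.00671 and 0.0118 in fry. Principal cells (0.00536) were up with adjusted p = 0.351 with an estimated correlation and 0.0426 in fry. Immediate early genes (1.85e-10), heat shock genes (3.49e-10), matrix genes (3.76e-10) and pericytes (9.99e-05) were down, each with adjusted p = 0.34 with an estimated correlation and with 0.0353, 0.0236, 0.0353 and 0.0277 in fry. Podocytes (0.000249), fatty acid oxidation (0.00281) and endothelium (0.00466) were down, with adjusted p = 0.355, 0.429 and 0.533 with an estimated correlation. Fry put these 3 at 0.0544, 0.0796 and 0.181, and it called 10 lists in all.

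The edgeR count in the 32 libraries was 1121 of 20686 genes, 507 higher and 614 lower (4361 at an unadjusted p under 0.05), and DESeq2 called 1817. With the animal tag as a fixed replicate block 16 genes passed (3 higher and 13 lower, 3865 at an unadjusted p under 0.05), and 15 of them were among the 1121. These were SREBF1 at 1.13 (adjusted p = 0.0192), NPR1 at -0.69 (adjusted p = 0.0413), EHD3, ACADVL, MID1IP1 and 1 gene without a symbol, and, named for this comparison after their values were seen, FASN, ETFB, LIPE, CSRP2, ECEL1, IRAK2, AGPAT2, SPRY4 and FCGRT. The other, CYR61, also named after its values were seen, passed with the block (-1.02, adjusted p = 0.0192) and not without it (-1.03, adjusted p = 0.0555). Under that block PDK4 was at -3.09 (adjusted p = 0.114), SLC14A2 at 2.71 (adjusted p = 0.15) and FLT4 at -1.08 (adjusted p = 0.0616). With the tag as a random block in limma-voom 1428 genes passed, these 3 at adjusted p = 0.00411, 0.00861 and 0.000446. Of the highest and lowest genes, 10 passed neither: GPR26, SLC14A1, RANBP3L, WNT7B, SLC6A12, ADAMTS4 and CCL24 (adjusted p from 0.0816 to 0.247 with the fixed and from 0.0564 to 0.121 with the random block), NR4A1 (-2.49 and -2.24, adjusted p = 0.199 and 0.127), NR4A3 (-2.03 and -1.88, adjusted p = 0.318 and 0.283) and NR4A2 (-1.39 and -1.21, adjusted p = 0.439 and 0.322). Libraries with a tag of their own add nothing to the group differences under the fixed block, so its 16 genes rest on fewer libraries than the 1121. If recurring tags mark the animals followed over time, the fixed block sets heart failure biopsies against recovery tissue taken after euthanasia. The mode of collection then cannot be told apart from recovery. Libraries with a tag of their own, 6 heart failure and 3 recovery, gave 40 genes. Among them were 2 of the 76 named calls, FLT4 and GLTP, and all 76 kept their direction. These libraries were also part of the fit that made the calls, so this direction was partly built in. With the term for presumed biopsies 56 of the 76 still passed, SREBF1 among them. With the medullary covariate there were 139 genes, SREBF1 among them (0.82, adjusted p = 0.0412). SLC12A1 (0.34, adjusted p = 0.469), PPP1R1A (0.64, adjusted p = 0.288) and ELOVL6 (0.47, adjusted p = 0.122) shrank and no longer passed. AQP2 no longer passed either (adjusted p = 0.0761), but its rise did not shrink (0.91, against 0.82 without the covariate). The groups of the time point label gave 189 genes. Removing single libraries gave 516 without recovery 3, 530 without recovery 5, 554 without recovery 6 and 714 without recovery 7.

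The comparison of recovery with baseline asks what still differed at the end. With all 35 libraries 1 gene passed, RPE, an enzyme of the pentose phosphate pathway, which rose by 0.74 (adjusted p = 0.0342, higher in 8 of 8). Its mean went from 64.5 CPM (SD 17.4, n = 14) to 108 CPM (SD 12.8, n = 8). In the 32 libraries 7 passed. RPE (0.61, adjusted p = 0.0189) and the chromatin gene KANSL1L (0.71, adjusted p = 0.0189) rose. CPT1A, the gate of fatty acid entry into mitochondria, fell by 1.00 (adjusted p = 0.0405), from 93.6 CPM (SD 26.8, n = 11) to 46.9 CPM (SD 9.17, n = 8). The mitochondrial carriers UCP2 (-1.60) and SLC25A33 (-0.79), FLT4 (-0.88) and the antibody receptor FCGRT (-0.62) fell at adjusted p = 0.049 each. All 7 shifted in 8 of 8 recovery libraries. AQP2 (0.08, adjusted p = 0.93), SLC12A1 (0.36, adjusted p = 0.826) and UMOD (0.27, adjusted p = 0.868) did not pass.

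By gene group, 2 of 36 fatty acid oxidation genes fell, CPT1A and UCP2 (10 adjusted over the list alone), with ACADVL (-0.56, adjusted p = 0.0533) and SLC25A20 (-0.68, adjusted p = 0.0856) not past the test. None of the 25 cholesterol genes passed over all genes (12 higher and 1 lower adjusted over the list alone, 15 at an unadjusted p under 0.05, 2 in DESeq2). The squalene enzyme SQLE stood at 0.87 and MSMO1 at 0.57 (adjusted p = 0.102 each). None of the 44 matrix genes passed (11 lower adjusted over the list alone, 18 at an unadjusted p under 0.05, 4 in DESeq2), and the proteoglycan BGN stood at -0.81 (adjusted p = 0.0628). None of the 22 pericyte genes passed (12 lower adjusted over the list alone, 12 at an unadjusted p under 0.05, 3 in DESeq2). Camera called 12 lists, 2 up and 10 down, with fatty acid oxidation down at 1.6e-05, matrix down at 3.94e-08 and cholesterol up at 3.94e-08. These had adjusted p = 0.385, 0.385 and 0.294 with an estimated correlation. It called 0 lists with an estimated correlation (4 at an unadjusted p under 0.05), and fry called 0 (9 at an unadjusted p under 0.05).

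The test behind these counts was edgeR's quasi-likelihood test, with 3871 genes of 20775 in the 35 libraries and 2340 of 20686 in the 32 at an unadjusted p under 0.05, against 370 and 198 called by DESeq2. With a fixed replicate block 0 genes passed in either set (2080 and 2015 at an unadjusted p under 0.05), with RPE at 0.57 (adjusted p = 0.496) and 0.33 (adjusted p = 0.422) and CPT1A at -0.91 (adjusted p = 0.389). Limma-voom with a random block called 1 and 5. Over all 35 libraries the count was 224 without baseline 6, and 2 without baseline 8, heart failure 4 or heart failure 9. It was 0 without baseline 2, 3, 4, 5, 7, 13 or 14, heart failure 10 or recovery 1, 2, 3, 4, 6, 7 or 8. In the 32 it was 25 without baseline 6, 11 without baseline 9 or 10 or heart failure 4, 10, 12 or 13, and 4 without baseline 13. It was 3 without baseline 5 or recovery 6, 2 without baseline 3 or 7, heart failure 1, 2 or 6 or recovery 5 or 8, and 0 without baseline 4 or recovery 1 or 7. The groups of the time point label gave 516 genes in the 35 libraries and 4 in the 32, and the term for presumed biopsies gave 0 and 32.

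A gene set that moved in heart failure and moved back in recovery was counted next. In the 32 libraries 152 genes passed both tests with opposite signs, 68 higher and then lower and 84 lower and then higher. The 10 with the strongest evidence and a symbol were PDE5A, the phosphodiesterase that ends cGMP signals (-0.47 in heart failure, 0.53 in recovery), the AMP kinase subunit PRKAG2 (-0.41, 0.49), the lipid carrier GLTP (-0.62, 0.68), AGFG2 (-0.68, 0.68) and SREBF1 (-0.83, 1.20). The others were FBXO7 (-0.35, 0.39), the death domain kinase RIPK1 (0.48, -0.52), CDKL2 (-0.80, 1.05), MID1IP1 (-0.62, 0.92), an activator of fatty acid synthesis, and the semaphorin receptor NRP2 (0.63, -0.74). AGFG2, PRKAG2, PDE5A, SREBF1, FBXO7, RIPK1 and NRP2 shifted in 13 of 13 heart failure libraries, the other 3 in 12 of 13, and all 10 shifted back in 8 of 8 recovery libraries.

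Both contrasts use the same heart failure libraries, which alone sets them against each other. In 20 simulations with no group effect the log2 changes of the 2 contrasts correlated at -0.42 across genes (genes are not independent replicates) and 0 genes passed both tests with opposite signs. With no group effect few genes can pass either test, so this 0 was close to fixed and does not measure what the shared libraries add. The data gave a correlation of -0.674 and 152 genes, where independence would give 6.14 and 5.12 genes in the 2 directions. With the heart failure libraries parted into 6 and 7, 1 part per contrast, the correlation was -0.423 and a median of 9.5 genes (0 to 25 over 20 splits) passed both ways, with medians of 54 and 298.5 calls. Over the 35 libraries edgeR called 0 such genes (860 at an unadjusted p under 0.05 in both tests, 114 in DESeq2), with a correlation of -0.293 against -0.435 simulated. 1 test over the 3 groups called 1169 genes in the 35 libraries and 1109 in the 32. With a fixed replicate block 0 genes passed the 3-group test in either set and 0 passed both ways in the 32 (415 of the 416 heart failure calls kept their direction). Limma-voom with a random block called 184 and 1310 in the 3-group test and 216 both ways. Without 1 library the 152 became 74 without baseline 6, 83 without baseline 11 or heart failure 5, 85 without baseline 1, and 88 without recovery 3. It was 91 without baseline 9, 92 without recovery 6, 94 without recovery 5, and 95 without heart failure 1, but 293 without heart failure 10, 374 without heart failure 9 and 498 without baseline 13. The 1109 became 606 without recovery 5, 678 without recovery 6, 682 without recovery 3, 696 without recovery 7, 721 without heart failure 5 and 1765 without baseline 13. In the 35 the 1169 became 679 without baseline 12 and 739 without baseline 14. The 0 both ways became 34 without baseline 2, 31 without heart failure 9, 26 without baseline 12, 23 without baseline 13, and 21 without baseline 14. It was 8 without heart failure 10, 4 without heart failure 4, 2 without heart failure 11 and 1 without baseline 5 or 11 or recovery 4.

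Libraries whose animal tag recurs and libraries with a tag of their own were compared because they were presumably collected differently. Within baseline and heart failure of the 32 libraries, 1323 genes differed by tag, 622 higher and 701 lower in shared-tag libraries. TFF3 (5.21), DIO2 (4.96), the thyroid hormone activating deiodinase, the neutrophil chemokine CXCL1 (3.25), FCGBP (3.00) and EYA2 (2.97) were the 5 highest. KIAA2018 (-2.08), UBN2 (-1.93), LRRC58 (-1.52), ZBTB20 (-1.47) and MDM4 (-1.46) were the 5 lowest. Among recovery libraries edgeR called 0 genes by tag (871 at an unadjusted p under 0.05), and no other tool was run on this test. With all 35 libraries 611 genes differed, led by ACTA1 (6.94) and CYP17A1 (-5.37), genes of the tissues seen in baseline 2 and 12.

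The heart failure change itself differed by tag for 4 genes in the 32 libraries, by a test of the difference. They included the elastic fibre gene FBLN5 (difference 1.42, SE 0.24), BGN (1.30, SE 0.21) and EMP2 (1.05, SE 0.17), at adjusted p = 0.0118 each. FBLN5 stood at 0.36 in shared-tag and -1.06 in own-tag libraries, BGN at 0.38 and -0.92, and EMP2 at 0.26 and -0.79. With all 35 libraries 2 genes differed, BGN among them (1.29, adjusted p = 0.0172). Heart failure against baseline called 2 genes in shared-tag (1570 at an unadjusted p under 0.05) and 273 in own-tag libraries (3332). Recovery against heart failure called 510 in shared-tag (4136) and 0 in own-tag libraries (2549), with 3 own-tag recovery libraries. Fitted on their own, the same libraries gave 2 genes with shared tags and 40 with own tags, so the order of the 2 counts depended on the fit.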

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

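The tests on the 3 baseline libraries with low kidney markers, the count of libraries behind the immediate early genes, the limit that voids the scaling test and the tests within 5 animals were chosen only after the result was seen, as was the set of 32 libraries.

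Among recovery libraries of the 32 set, 3 of 89 values tested had 1 library far from the other 7, where chance gives about 1 in 20. The gap over the range was 0.55 for HSP90B1 (recovery 2 highest), 0.568 for TEF (recovery 7 highest) and 0.593 for WNT9B (recovery 1 lowest).

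The change from baseline to heart failure differed between shared-tag and own-tag libraries for 2 genes in the 35 libraries and 4 in the 32, by a test of the difference. The differences were 1.29 for BGN in the 35, and 1.42 for FBLN5, 1.30 for BGN and 1.05 for EMP2 in the 32.

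Baseline 2, 12 and 14 held few kidney transcripts and many of other tissues. Low depth is argued against, since their lowest total was 15.4 M counts and another library had 14.3 M. Another tissue taken or mixed in may account for them: in 3 of 3, a list for adrenal, muscle or pericytes and smooth muscle lay above the highest of the other 32 libraries, at a median log2 CPM of 7.36 in baseline 2 (adrenal), 12.19 in baseline 12 (muscle) and 7.04 in baseline 14. A swap of labels with a heart failure or recovery library would change the group name and not the transcripts, so it cannot account for the low kidney markers. Whether such a swap placed them in baseline stays open. For that question, 0 libraries outside baseline fell below the kidney marker limit, and a swap would leave that count at 0 too. No biological explanation was tested, and a wrong label from outside the series stays open as well.

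The mean of 4 medullary genes (SLC14A1, SLC14A2, SLC6A12, WNT7B) stood at -1.45 log2 units in heart failure over the 32 libraries (SE 0.76, permutation p = 0.0577), a difference that did not pass. The share of medulla in each sample is consistent with the values within groups, where their mean ran against the podocyte list, a marker of cortex (Pearson r = -0.669, permutation p = 0.00019, adjusted 0.00076 over 4 relations, Spearman rho = -0.635, p = 0.00085, n = 32, r = -0.642 without the 2 farthest libraries), and with the loop of Henle list without SLC14A2 (r = 0.586, permutation p = 0.00051, adjusted 0.00102, rho = 0.585, p = 0.00065, r = 0.525 without 2). The other relations were with the proximal tubule list (r = -0.321, permutation p = 0.0759, adjusted 0.0759, rho = -0.328, p = 0.0573, r = -0.253 without 2) and the collecting duct list without SLC14A2 (r = 0.392, permutation p = 0.0332, adjusted 0.0443, rho = 0.323, p = 0.0894, r = 0.251 without 2). The mode of collection stays open, with -1.78 (SE 0.94, exact permutation p = 0.0606) in own-tag and -1.24 (SE 1.27, exact permutation p = 0.314) in shared-tag libraries, or -1.38 (SE 1.41, exact p = 0.375) within the 5 animals with both, because no label gives it. An effect of heart failure on the medulla itself stays open too. In recovery the mean of the 4 genes stood at 4.02, 5.52, 4.79, 2.36 and 4.87 in shared-tag libraries and at 0.22, -0.34 and 5.30 in own-tag libraries. In heart failure the means were 0.79 in shared-tag and -0.24 in own-tag libraries. For the rise of these genes in recovery, mode of collection and share of medulla could not be told apart from a change after pacing.

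Immediate early genes had higher values in heart failure, by 0.65 log2 units on average (SE 0.28, permutation p = 0.0357) over the 32 libraries. The mode of collection could not be told apart from heart failure, with 0.61 (SE 0.39, exact permutation p = 0.113) in own-tag and 0.60 (SE 0.34, exact permutation p = 0.172) in shared-tag libraries, or 0.19 (SE 0.19, exact p = 0.375) within the 5 animals with both, since handling before freezing may raise these genes and no label gives it. A few libraries could carry part of it: 9 of 13 heart failure libraries lay above the baseline median, with heart failure 11 at 5.35 and heart failure 5 at 5.06 log2 CPM. The test of scaling between libraries could not decide, since RLE factors left the list's median at 0.922 against 0.925 with TMM (ratio 0.996) but moved all genes by a median of only 0.00473. Scaling shifts all genes of a library alike, and the median change over all genes was -0.002 with TMM. These values argue against scaling for the gap between the list and the other genes. A response to heart failure stays open.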

How the results depend on the processing

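The set of 32 libraries with all its alternatives and the medullary covariate were chosen only after the result was seen. Counts are given in the order heart failure against baseline, recovery against heart failure, recovery against baseline, 3-group test and opposite directions, where each left 1.5 times the reported count, and the cause was not tested except where fewer samples or a higher limit give it.

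In the 35 libraries (1217, 1, 1, 1169 and 0 genes), a fixed replicate block gave 0, 0, 0 and 0 in the first 4 (1752, 1525 and 2080 at an unadjusted p under 0.05 in edgeR), and a random block in limma-voom 268, 43, 184 (3-group test) and 11 (opposite). Shared-tag libraries alone gave 0, 0, 0 and 0 in the first 4. Own-tag libraries alone gave 83 in heart failure, 0 in recovery against baseline, 32 in the 3-group test and 1 opposite. A term for the shared tag gave 0 in recovery against baseline. The presumed biopsy term gave 721 in heart failure, 0 in recovery against baseline and 348 in the 3-group test. Time point labels gave 0 in recovery against heart failure and 516 against baseline, and leaving out both disagreeing libraries 2 against baseline. Upper-quartile factors gave 2, 0 and 1 (recovery against heart failure, against baseline, opposite), DESeq2 331, 370 and 114. No filter gave 0 in recovery against baseline and 365 genes by shared tag (611 reported). The 2 surrogate variables gave 284, 559, 3, 591 and 85. A log2 change of at least 1 left 678 in heart failure, 0 in recovery against baseline and 746 in the 3-group test. Without baseline 2, 12 and 14 the counts were 416, 1121, 7 and 152 opposite.

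In the 32 libraries (416, 1121, 7, 1109 and 152 genes), a fixed block gave 0, 16, 0, 0 and 0 (1092, 3865 and 2015 at an unadjusted p under 0.05 in the pairwise tests of edgeR), shared-tag libraries alone 0, 2, 0, 0 and 0 (1158, 3457 and 1533), and own-tag libraries alone 40 in recovery against heart failure, 0 against baseline, 367 in the 3-group test and 26 opposite. For heart failure against baseline own-tag libraries alone called 558 genes, against the 0 of shared-tag libraries alone. The terms for shared tag and presumed biopsy gave 13 and 32 in recovery against baseline. Time point labels gave 189, 4, 384 and 44 in the last 4. RLE factors gave 4 and no filter 3 in recovery against baseline. DESeq2 gave 1006, 1817, 198, 2086 and 439, and surrogate variables 1430, 2258, 75, 2590 and 601. The medullary covariate gave 235, 139, 305 (3-group test) and 32 (opposite). A log2 change of at least 1 left 90, 274, 1, 276 and 41. Camera's 52 list calls in the 35 libraries became 0 with an estimated correlation and 0 in fry, and its 42 in the 32 became 0 and 10. Of the named calls in the 32 libraries, 0 of 59, 8 of 76 and 0 of 7 still passed in the pairwise tests with the fixed block (all in the same direction), and 38 of 59, 61 of 76 and 4 of 7 with the random block. The same libraries had given the calls, so the shared direction was partly built in. The 8 were SREBF1, EHD3, ACADVL, NPR1, MID1IP1, FASN, ETFB and LIPE, the last 3 named for that comparison after their values were seen. In the 35 libraries 0 of 26, 0 of 1 and 0 of 1 passed with the fixed block, and 8 of 26, 1 of 1 and 1 of 1 with the random block.

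Leaving out 1 library at a time gave 564 to 1687, 1 to 101 and 0 to 224 genes in the pairwise tests of the 35 libraries, 679 to 1481 in the 3-group test and 0 to 34 opposite. In the 32 these were 175 to 1142, 516 to 1473, 0 to 25, 606 to 1765 and 74 to 498.

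Of the named genes, ATP2A1 in heart failure (35 libraries) turned to 0.83 in own-tag libraries, 0.37 in DESeq2 and 0.35 with surrogate variables, and CAPN8 (32 libraries) to 0.05 in own-tag libraries. With the medullary covariate, built from 3 of these genes, SLC14A1 came to 0.00, RANBP3L to -0.20, WNT7B to -0.17 and SLC6A12 to -0.75 in recovery against heart failure. With a replicate block camera turned the direction of oxidative phosphorylation (adjusted p = 0.887 in heart failure, 0.154 in recovery) and adipocyte genes (0.492 in heart failure). Among the other values of named genes in the 32 libraries, 1715 kept direction and side of the threshold, 717 kept direction and no longer passed, and 31 newly passed, and in the 35 libraries 273 and 135 did the former. For lists these were 221 and 112. At the depth and number of libraries here, simulated changes of 1.5 times were recovered in 14.9% to 52.2% of genes, with each gene drawn independently.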

Other observations

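The 32-library values here, and the set itself, were chosen after the result in all libraries was seen.

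Circadian clock genes moved in both directions in the 32 libraries. In heart failure the repressor CIART fell by 1.44 (adjusted p = 0.00569, lower in 13 of 13) and NFIL3 rose by 1.18 (adjusted p = 0.00959, higher in 13 of 13), of 19 genes (4 higher and 6 lower adjusted over the list alone). In recovery against heart failure the clock output factors TEF (0.62, adjusted p = 0.012) and DBP (1.10, adjusted p = 0.0254) and CRY2 (0.49, adjusted p = 0.0136) rose and ARNTL, which drives the clock, fell by 0.72 (adjusted p = 0.0174), each in 8 of 8 (9 higher and 4 lower adjusted over the list alone). Camera did not call the list (adjusted p = 0.594 and 0.0655), while fry's mixed test, for change either way, gave 0.00432 and 0.00213. The labels give no hour of collection.

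Of 33 interferon response genes edgeR called 0 in heart failure in the 32 libraries (18 at an unadjusted p under 0.05, 1 higher adjusted over the list alone, 3 in DESeq2), with a median of 0.62, and camera put the list up at 6.19e-06, with adjusted p = 0.762 with an estimated correlation. In recovery IRF9, which carries the interferon signal to the nucleus, fell by 1.09 (adjusted p = 0.0211, lower in 8 of 8; 13 lower adjusted over the list alone), and camera put the list down at 1.68e-06, with adjusted p = 0.459 with an estimated correlation. Macrophage markers had 0 of 25 genes called by edgeR in either comparison (4 and 5 at an unadjusted p under 0.05, 1 and 2 in DESeq2), with camera at 0.00317 up and 0.00153 down, and adjusted p = 0.796 and 0.53 with an estimated correlation. Of 50 oxidative phosphorylation genes NDUFA9 fell by 0.22 in heart failure (adjusted p = 0.0427, lower in 12 of 13), and camera put the list down at 3.76e-07, with adjusted p = 0.762 with an estimated correlation. In recovery against heart failure 7 of 26 glucocorticoid response genes fell (10 adjusted over the list alone), RASD1 by 1.57 and CEBPD by 1.17, and 4 of 36 hypoxia genes fell (5 adjusted over the list alone), EPAS1 by 0.54, with fry at 0.0312 and 0.0353 and adjusted p = 0.34 each with an estimated correlation.

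The median, mean and camera test did not all have the same sign for 8, 4 and 5 of 36 lists in the 32 libraries (heart failure against baseline, recovery against heart failure, recovery against baseline) and for 11, 4 and 9 in the 35. Among the 8 were the natriuretic list (median 0.01, mean -0.09, test down at 0.653), hypoxia (-0.002, 0.04, up at 0.689), pericytes (-0.10, 0.01, up at 0.634), B and plasma cells (0.06, -0.01, up at 0.226), neutrophils (0.17, -0.14, up at 0.296), distal convoluted tubule (0.05, -0.03, up at 0.756) and ribosomal proteins (-0.005, 0.01, up at 0.874). Among the 9 were intercalated cells (-0.04, -0.06, up at 0.029) and medullary genes (0.17, -0.39, up at 0.0231), with adjusted p = 0.714 and 0.598 with an estimated correlation. In heart failure against baseline of the 35 libraries the principal cell list had a median of -0.03 and a mean of -0.14 with camera up at 0.0186, and adjusted p = 0.803 with an estimated correlation.

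Group labels were dealt again in 100 splits of the samples, the real one included. In the 32 libraries only the real split, 1 of 100, was as large for heart failure against baseline (416 genes, highest other 30) and recovery against heart failure (1121, highest other 177). The same held for recovery against baseline (7, highest other 4) and the test over 3 groups (1109, highest other 37). No smaller share can be reached with 100 splits, and the dealing did not repeat the choice of the 32 libraries. With the tag as a fixed replicate block these 4 tests gave 0, 16, 0 and 0 genes. The 7 became 0 without baseline 4. Opposite directions (152, highest other 2) were also as large in 1 of 100. But the other splits had a median of 0 calls in each contrast, so this count was close to fixed and does not test a move back. With the heart failure libraries parted, a median of 9.5 genes passed both ways (0 to 25). Labels were next dealt within animals for shared tags only, and freely among the libraries with a tag of their own. The highest others were then, in the same order, 1, 11, 1, 21 and 0, again with 1 of 100 as large. Chance cannot be excluded for the 42 list calls by camera, which 24 of 100 splits matched under either way of dealing (highest other 56 and 57).

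In the 35 libraries 1 of 100 splits had a count as large for heart failure against baseline (1217 genes, highest other 593). For the test over 3 groups 2 of 100 did (1169, highest other 2906). These counts cannot tell a group effect from the place of the 3 libraries with low kidney markers. All 3 are in baseline, and labels were dealt over any library. Animal tags were not kept in the dealing either, and with the tag as a fixed replicate block 0 genes passed in both tests. Chance cannot be excluded for recovery against heart failure (1 gene, 54 of 100, highest other 3447). The same holds for recovery against baseline (1, 53 of 100, highest other 3633) and the 52 list calls (8 of 100, highest other 65). It also holds for opposite directions (0, 100 of 100, highest other 67). There 860 genes had an unadjusted p under 0.05 and DESeq2 called 114, against 0 by edgeR. The 3 highest gene counts, 3447, 3633 and 2906, came from 1 split, which points to a structure of the samples, and no test tied it to particular libraries. With tags dealt again within groups, the difference between shared and own tags was as large in 1 of 100 splits in the 32 libraries (1323 genes, highest other 72) and in 2 of 100 in the 35 (611, highest other 1306). The tag's effect on the heart failure change was as large in 4 of 100 in the 32 (4 genes, highest other 825) and in 6 of 100 in the 35 (2 genes, highest other 975). The 825 and the 975 each came from 1 split, which points to a structure of the samples that was not traced.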
